A study of Mus musculus with 7 samples.

How the data were processed

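Chromatin of C2C12 cells was cross-linked with formaldehyde, sheared by probe sonication and immunoprecipitated, per the labels' protocols, and 7 libraries were described, 1 for each combination of cell line and antibody. A processed file of 1 library, anti-Six4 in the shNS control line at 24 h, was analysed here; the other 6 were not analysed here. It is a peak list with 3 columns (chromosome, start and end), deposited by the authors without a header, score, fold enrichment, p-value or summit. The submitters' processing notes name Bowtie (an aligner), Picard, bedtools and MACS2 version 2.0 (a peak caller) and the mm9 build. They are given without roles, order or parameters, so the threshold, the control library and any filter are not given in the sources used here. Starts were counted from 0 in the file and are printed from 1.

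The build was checked against the gene table at hand, which is of GRCm38. On 10 of 20 chromosomes the last peak lay past the last gene of that table, which does not by itself settle the build. The peaks were taken to be in mm9, as the submitters' processing notes name it, and no position was taken from that table. No mm9 sequence or annotation was used here. For this reason the planned shares of peaks at promoters and in exons and introns, the test of 14 gene lists (288 genes) and the search for 12 motifs, among them the MEF3 site of muscle promoters, were not run, nor was the rule that would have named genes. That rule asked, without annotation, for the 10 highest-scoring peaks. As the list has no score, the first 10 lines were named in their place, and the longest peaks, densest windows and largest runs were named after their values were seen. The planned test of peak counts against chromosome length was replaced by description, because chromosome lengths of the build were not used either. The distance from first to last peak stood in for the length.

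Peaks per Mb were computed over that distance with exact Poisson 95% intervals, which cover counting error only. Windows of 1 Mb lying wholly between the first and last peak were counted by peak midpoint. Bootstrap draws of windows, 2000 in number, gave intervals that allow for uneven spread but treat neighbouring windows as independent. Neighbours were peaks whose midpoints lay within 10 kb. The observed share was set against 100 shuffles of the midpoints along each chromosome, and 100 within each peak's own 1 Mb window, without exclusion of assembly gaps. Runs were peaks with edge-to-edge gaps of at most 5 kb, and 20 shuffles of each kind were drawn for them. Pairs were counted at 2 to 5 kb and 5 to 8 kb between midpoints, each pair once, with exact binomial intervals that treat pairs as independent. Shares have exact Clopper-Pearson intervals. Wide peaks were those of at least 1 kb, compared with Fisher's exact test. Peaks within a library are not replicates, and no value here measures variation between cultures.

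The density ratio and the neighbour share were tested on simulated data. Uniform peaks with a planted X to autosome ratio of 1 or 0.5 gave mean estimates of 1.00 and 0.50 over 20 simulations of 58528 peaks each. With a ratio of 1 their neighbour share of 36.7% differed little from its shuffle at 36.6%. Because these peaks were uniform over the same spans, this checks the code only. It does not show how the measures or intervals behave on unevenly spread peaks. Alternatives fixed before the data were examined, for the number, width and covered length of the peaks only, were the merging of peaks under 500 bp apart and the removal of peaks on Y, M or unplaced sequence. The X to autosome ratio, the neighbour, run, listed-order and pair analyses, the bootstrap and all other alternatives, these 2 on any other result included, were chosen after the data had been seen. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.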

Results

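Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where Six4, a homeodomain transcription factor of the sine oculis family, lies on the genome of differentiating C2C12 cells. C2C12 is a mouse myoblast line that leaves the cell cycle and forms myotubes when the serum in its medium is lowered. The series holds 7 libraries, each the only one of its kind, and all were labelled as 24 h of differentiation. They are an anti-Six4 library from the control hairpin line (shNS), an anti-Six4 library from a line with Six4 stably knocked down, an anti-Flag library from a line carrying a Flag-tagged Six4, anti-Flag and rabbit IgG libraries from the parental line, and input DNA from the parental and shNS lines. The values below come from 1 of them, the authors' peak list for anti-Six4 in the shNS line. The other 6 libraries were not analysed here, so the contrasts of control with knockdown cells, and of tagged with parental cells, were not made. There was no replicate, and the intervals given describe counting or sampling of regions within this library only. The read depth behind the peaks is unknown.

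The list placed anti-Six4 peaks at 58528 regions of the mm9 genome, on all 19 autosomes and on chromosome X. How many of them depend on Six4 is not known, because the knockdown, IgG and Flag libraries were not analysed here. The peaks were short. The median width was 275 bp, with quartiles of 204 and 454 bp, and the longest peak reached 5517 bp. In total they covered 23.5 Mb, which was 0.915% of the 2571 Mb between the first and last peak of each chromosome. Peaks of at least 1 kb were a minority of 3751 (6.41% of the list), yet they held 21.8% of the covered length. At the other end, 2972 peaks (5.08%) had exactly the shortest width in the list, 165 bp, while no other width occurred more than 355 times. No line was repeated, no peaks overlapped, and the smallest gap between neighbours was 52 bp.

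The longest peak lay on chromosome 10 from 79610497 to 79616013 (5517 bp). It was followed by peaks on chromosome 11 from 51668825 to 51672729 (3905 bp), chromosome 5 from 139468713 to 139472559 (3847 bp), chromosome 13 from 63664288 to 63668011 (3724 bp) and again chromosome 10 from 13684293 to 13688014 (3722 bp). The peak on the first line of the list lay on chromosome 1 from 55144197 to 55145572 (1376 bp). The next 4 lines were peaks on chromosome 17 from 28313563 to 28315023 (1461 bp), chromosome 5 from 124356934 to 124357810 (877 bp), chromosome 7 from 117204401 to 117205865 (1465 bp) and chromosome 18 from 7004404 to 7005421 (1018 bp). Lines 6 to 10 held peaks on chromosome 9 from 108418904 to 108420354, chromosome 2 from 156005108 to 156006427, chromosome 5 from 136253773 to 136254972, chromosome 2 from 34726130 to 34726854 and chromosome 3 from 135100743 to 135102661. The genes at these positions were not identified, because no annotation of this genome build was used here.

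Chromosome 11 had the most peaks per Mb and chromosome X the fewest. Chromosome 11 carried 4195 peaks, or 35.3 per Mb (exact Poisson 95% interval 34.3 to 36.4). Chromosome 15 followed with 32.7 per Mb (31.6 to 33.8), then chromosome 19 with 28.7 (27.4 to 30.2) and chromosome 17 with 28.2 (27.1 to 29.3). Chromosome 7 was the sparsest autosome at 17.6 per Mb (16.9 to 18.2), so that the autosomes spanned a 2.01-fold range. The span of chromosome 7 includes the longest stretch without a peak, 7.37 Mb, and assembly gaps were not excluded from any span. Chromosome X carried 1413 peaks, or 8.68 per Mb (8.24 to 9.15). Because peaks were unevenly spread along each chromosome, the Poisson intervals are too narrow for comparing chromosomes. Resampling of 1 Mb windows gave wider ones, but it treats neighbouring windows as independent, so these may still be too narrow. By that measure chromosome 11 averaged 34.9 peaks per window (30.8 to 39.2) and chromosome 15 averaged 32.6 (27.4 to 37.9), which overlap. Chromosome 7 averaged 17.4 (14.5 to 20.1) and chromosome X 8.65 (7.15 to 10.4), which do not.

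**Figure D1:**
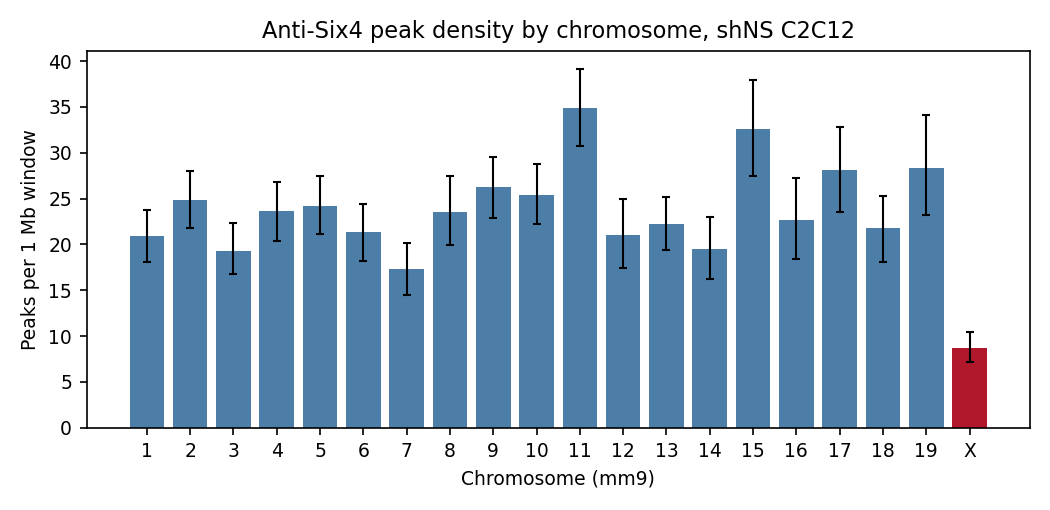
Mean number of anti-Six4 peaks per 1 Mb window (vertical axis) on each mm9 chromosome (horizontal axis) in the single shNS library; bars start at 0, whiskers are 95% bootstrap intervals over windows, autosomes are blue and X is red. Chromosome 11 stands highest at 34.9 and X lowest at 8.65. The whiskers treat neighbouring windows as independent and may be too narrow.

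The density on chromosome X was 0.366 times that of the autosomes together, 8.68 against 23.7 peaks per Mb. The 95% bootstrap interval of this ratio was 0.302 to 0.437 over 1 Mb windows and wider, 0.242 to 0.472, over 10 Mb windows. The 19 autosomes had a mean of 24.2 ± 4.55 peaks per Mb (SD over chromosomes). Windows without a single peak made up 13.6% of the 162 windows of X and 4.11% of the 2383 autosomal windows. The median width was 247 bp on X (bootstrap interval over peaks 241 to 255 bp) and 276 bp over all autosomes, but X did not stand apart by width, since chromosomes 13 and 3 had medians of 248 and 251 bp. Peaks of at least 1 kb were 60 of 1413 on X (4.25%) and 3691 of 57115 on the autosomes (6.46%), an odds ratio of 0.642 (Fisher's exact test, two-sided p = 0.000514). That test compares peaks within 1 library, and peaks are not replicates. Among autosomes, the share of such wide peaks ran from 4.63% on chromosome 16 (exact binomial interval 3.78 to 5.60%) to 8.45% on chromosome 19 (7.16 to 9.89%).

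Within chromosomes, peaks were gathered in some regions and rare in others. The count per 1 Mb window had a median of 17 and quartiles of 5 and 37 over 2545 windows, and its variance was 18.0 times its mean. The densest 10% of windows held 28.0% of the windowed peaks, against 13.9% for random counts of the same mean. The densest single window, on chromosome 15 from 102000001 to 103000000, held 103 peaks. It was followed by chromosome 8 from 87000001 to 88000000 with 98 peaks, and by chromosome 1 from 137000001 to 138000000 and chromosome 15 from 81000001 to 82000000 with 89 peaks each. Chromosome 16 from 91000001 to 92000000 held 86 peaks. Of the 10 densest windows, those on chromosome 15 also included 100000001 to 101000000 with 83 peaks and 76000001 to 77000000 with 82 peaks. At the opposite extreme, 120 windows were empty, and the longest stretch without a peak ran over 7.37 Mb of chromosome 7, from 39155445 to 46529844. Assembly gaps and unmappable sequence were not excluded, so an absence of peaks there need not mean an absence of binding.

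At short range, 57.5% of peaks had another peak within 10 kb, measured between midpoints. Peaks placed at random along each chromosome gave 37.9% on average, and none of 100 such shuffles reached the observed share (highest 38.4%). Peaks shuffled only within their own 1 Mb window gave 51.6% (highest 52.1%). The excess over this regional expectation was not present at every distance. Within 0.5 kb, 3.23% of peaks had a neighbour against 3.88% after regional shuffling, below all 100 shuffles, but shuffled peaks could overlap and listed ones did not. Within 1 kb the shares were 10.7% and 7.56%. Within 5 kb they were 31.8% and 31.6%, and 30 of 100 shuffles matched or exceeded the observed share. When peaks under 500 bp apart were merged in the list and in the shuffles alike, the shares were 1.73% against 1.07% within 1 kb and 52.5% against 48.2% within 10 kb, above all 100 regional shuffles, but 23.7% against 26.6% within 5 kb, below all of them. Most peaks stood alone: 38465 (65.7%) were more than 5 kb from any other peak, edge to edge.

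Runs of at least 5 peaks with no gap above 5 kb were found at 98 places and held 556 peaks, 0.950% of the list. Uniform shuffles gave 12.2 such runs on average, at most 17 in 20 draws, whereas shuffles within 1 Mb windows gave 115.7, at most 134. The runs with the most peaks had 10 each, on chromosome 12 from 52851490 to 52876944 and on chromosome 1 from 90127038 to 90157046. Runs of 9 peaks lay on chromosome 8 from 87499967 to 87522388, inside the second-densest window of the genome, and on chromosome 10 from 24596958 to 24621325. Peaks covered 31.4% of the run on chromosome 8 and 11.8% of the run on chromosome 10. Chromosome X held 2 of the 98 runs.

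The list was not in genome order (Spearman's rho between line number and genome position was 0.03), and its order carried information although no score was included. Across peaks, line number and width had a Spearman's rho of -0.64, outside the range of 100 shuffled orders (-0.01 to 0.01). The first 10% of the list had a median width of 797 bp, the next 10% 574 bp and the last 10% 203 bp. Chromosome X supplied 0.820% of the first 10% of lines (exact binomial interval 0.605 to 1.09%) and 4.99% of the last 10% (4.45 to 5.58%). Chromosome 11 went the other way, from 9.19% (8.46 to 9.96%) to 4.46% (3.95 to 5.02%). Counts per 1 Mb window were also more uneven for early lines, with a variance of 4.68 times the mean in the first 10% of lines and 1.84 times in the last 10%. What quantity the authors ordered the list by is not stated in the sources used here.

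**Figure D2:**
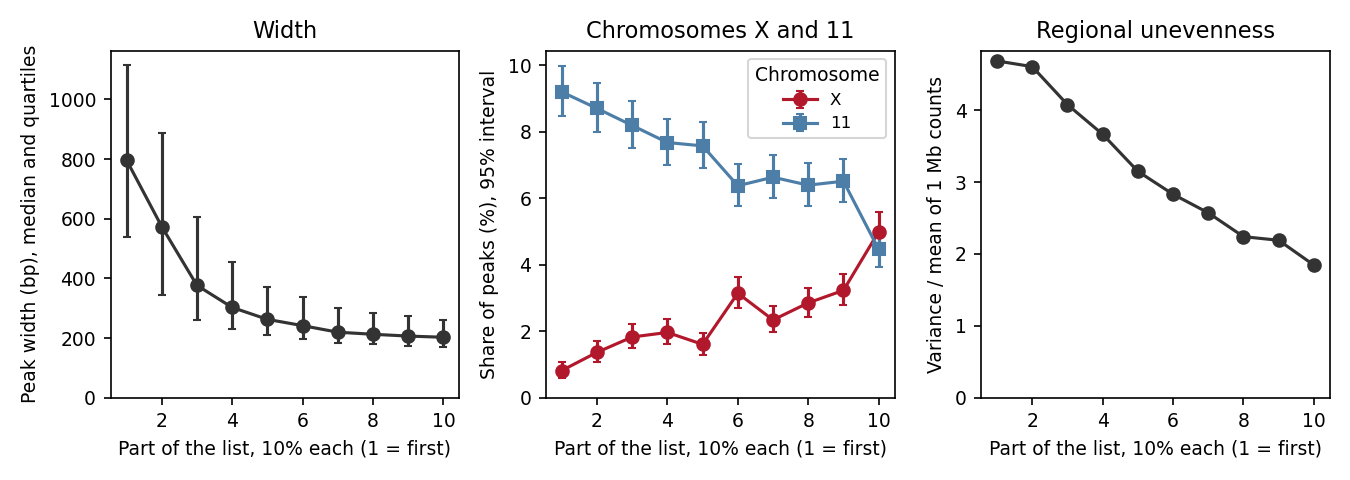
Properties of the anti-Six4 peaks in successive 10% parts of the list (horizontal axes, 1 is the first listed): median width in bp with quartiles (left), percent of peaks on chromosomes X and 11 with 95% exact binomial intervals (middle), and variance over mean of counts in 1 Mb windows, without unit (right). Median width falls from 797 to 203 bp, while the X share goes from 0.820 to 4.99%.

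Late-listed peaks were scarce between 2 and 5 kb of early-listed ones. Around peaks of the first 10% of lines, peaks of the last 50% of lines occurred 60 times at 0.5 to 1 kb, 33 times at 4 to 5 kb, 172 times at 5 to 6 kb and 200 times at 6 to 7 kb. At 2 to 5 kb there were 91 such pairs and at 5 to 8 kb, an equal length of sequence, there were 596. The ratio was 0.153 (exact binomial 95% interval 0.121 to 0.191), and 100 shuffles within 1 Mb windows gave 0.851 to 1.17. All 20 chromosomes had fewer pairs at the shorter distance, from 2 against 35 on chromosome 8 to 6 against 20 on chromosome 18. Pairs within the first 10% of lines showed no such difference, with 166 and 150 pairs, a ratio of 1.11 (0.882 to 1.39). The neighbour shares and runs given above therefore count a list in which late-listed peaks are scarce up to 5 kb from early-listed ones.

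**Figure D3:**
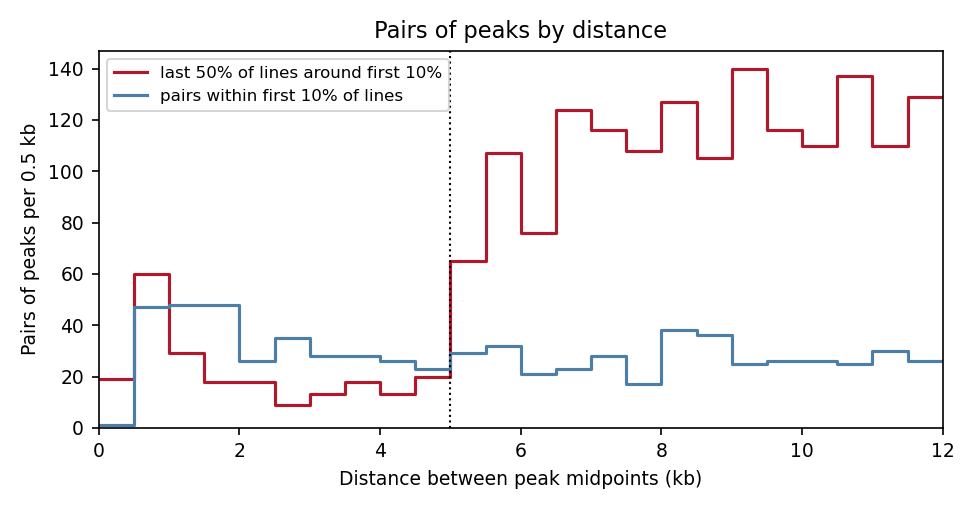
Number of pairs of peaks per 0.5 kb of distance (vertical axis) against the distance between midpoints in kb (horizontal axis); the red line pairs the last 50% of lines with the first 10%, the blue line counts each pair within the first 10% once, and the dotted line marks 5 kb. The red line rises from 20 pairs in the bin before 5 kb to 65 and 107 in the next bins, and the blue line shows no step there, with 23, 29 and 32 pairs.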

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

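Merging peaks under 500 bp apart and removing peaks on Y, M or unplaced sequence (there were none) were planned for the number, width and covered length of the peaks; all else was chosen after seeing the data. Alternatives on score could not be run, since the list has no score, nor could those on promoters, gene lists and motifs. There were 35 recomputed values. No direction reversed among the ratios and differences, while peak number, width and covered length have no direction that could reverse. Of the 35, 27 stayed within set limits. The limits were 1.5 times for numbers, lengths and neighbour ratios, 1 SD over peaks for widths, and the 95% interval for the X and pair ratios. These limits are wide. A neighbour ratio of 1.11 against 1.52 and a median width of 454 against 275 bp both counted as within them. Removing peaks on Y, M or unplaced sequence removed none, so its values could not move. The neighbour share within 5 kb, which fell below the regional shuffles when both were merged, is not among the 35. By construction the peak number fell to 29264 in the first 50% of lines, 1000 in the first 1000 lines and 29329 among peaks of at least the median width. In the first 1000 lines the median width was 863 bp and the covered length 0.964 Mb. The ratio of X to autosome density moved from 0.366 to 0.228 in the first 50% of lines and 0.119 in the first 1000 lines, and lay between 0.312 and 0.406 under the other settings. The observed over shuffled share of peaks with a neighbour within 10 kb was 1.52 for the whole list. It moved to 3.47 in the first 1000 lines, 2.19 in the first 50% and 2.09 among peaks of at least the median width. Shorter lists have lower shuffled shares and so more room for a high ratio, so these rises do not by themselves show closer spacing. For the whole list the ratio was 1.44 after merging (1.49 with shuffles merged alike) and 1.11 against shuffles within 1 Mb windows. Ranking by width in place of line number gave a ratio of pairs at 2 to 5 kb over 5 to 8 kb of 0.128, against 0.153. The read depth is unknown, so how many weaker sites went uncalled cannot be stated.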

Other observations

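The tests in this part were chosen after the peak list had been opened. Those of the distal ends, of merging, of regional shuffling, of X windows holding a peak and of the X share by line had their expected outcomes written before their results were seen; those of the step at 5 kb, of chance on X and of merging the shuffles alike did not.

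Peaks were denser toward the distal end of most chromosomes, which in the mouse is the end away from the centromere. The last 10% of the span held 30.0 ± 13.2 peaks per Mb and the first 10% held 20.2 ± 11.1 (SD, n = 20 chromosomes). The distal end was higher on 16 of 20 chromosomes, by 9.73 ± 12.3 peaks per Mb on average (sign-flip permutation test with 100000 draws, two-sided p = 0.0027). On chromosome 15 the difference was 68.2 against 36.9 peaks per Mb, and on chromosome 5 it was 37.5 against 11.9. Chromosomes 17, 18, 19 and X went the other way; chromosome 19 had 55.3 peaks per Mb in its first 10% and 39.1 in its last. With 20% in place of 10% of the span the difference was 8.54, and leaving out any single chromosome kept it between 8.59 and 11.1. Gene density along chromosomes was not used here, so whether the gradient follows it was not tested.

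The scarcity of late-listed peaks around early-listed ones ended abruptly at 5 kb, and a candidate explanation is the peak caller. MACS2 judges each peak against a local background, by default in windows up to 10 kb wide. Whether that background came from a control library or from the anti-Six4 library itself is not known here. Only where it holds the signal of a strong peak is the bar raised for a weaker neighbour. The deficit would then deepen with the strength of the neighbour; strength is not in the list, but by line number the ratio of pairs at 2 to 5 kb over 5 to 8 kb was 0.153 around the first 10% of lines, 0.279 around the next 10%, 0.462 around the 10% after that and 0.588 (0.527 to 0.655) around the lines between 40% and 50%. It eased no further than that: it was 0.563 around the lines just before these and 0.550 (0.511 to 0.592) within the last 50% of lines, so a deficit was present around late-listed peaks too. Peaks of any strength being scarce around a strong peak stays open: the ratio was 1.11 (0.882 to 1.39) within the first 10% of lines but 0.654 (0.491 to 0.866) within the widest 10% of peaks, and neither line number nor width is known to measure strength. A lack of weak sites only was not tested. Whether the calling used a control library, and which, is not known either. If the caller explanation holds, weak sites up to 5 kb from strong ones are under-counted in this list.

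Chromosome X had fewer peaks than the autosomes, and most clearly among early lines. Chance variation between regions is argued against by a permutation of 10 Mb windows (two-sided p = 3e-05 from 100000 draws). X had 15 windows with 83.9 ± 53.8 peaks and the autosomes 220 with 235 ± 122 (SD). The test treats windows as exchangeable, although autosomes themselves spanned a 2.01-fold range and X is a single chromosome. Its p-value therefore does not measure spread between chromosomes, and the comparison was chosen after the data had been seen. Stretches of X without any peak at the 1 Mb scale are not the whole cause, since windows that hold a peak still gave a ratio of 0.406 (0.338 to 0.481). A lower read depth over X stays open. The X share was 4.17 percentage points higher in the last 10% of lines than in the first 10%, whereas the outcome first written for this explanation was a lower share. The test cannot decide, because a uniformly weaker signal could also move X peaks down a list ranked by signal. Whether this list is so ranked is not known. Copy number of X in this line, shorter unmappable sequence and a biological difference in Six4 occupancy were not tested, and the input library that bears on depth was not analysed here.

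Peaks lay closer together than uniform placement gives. Splitting of broad regions by the peak caller into peaks under 500 bp apart is not the whole cause. After such peaks were merged, the share with a neighbour within 10 kb was still 1.44 times the shuffled share (1.49 times with the shuffles merged alike). Splitting into peaks further apart was not tested. Regional density at the 1 Mb scale is not the whole cause either: shuffling within 1 Mb windows kept 0.897 of the observed share (51.6% against 57.5%), only just under the 0.9 set as the bound, and none of 100 such shuffles reached it. With merging and regional shuffling together 0.919 was kept, above that bound. Yet again no shuffle reached the observed share (52.5% against at most 48.8%). Both together could thus account for much of the excess but left a small part. The shuffles did not exclude assembly gaps or unmappable sequence within windows, which could lower their shares. Whether that accounts for the part left was not tested. These readings are for 10 kb. Within 5 kb regional shuffling gave 31.6% against 31.8% observed, and with merging alike 26.6% against 23.7%. Runs of at least 5 peaks were also no more frequent than after regional shuffling (98 against 115.7 on average). The deficit of late-listed peaks up to 5 kb may lower such shares, but its effect on them was not tested.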
